A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

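Total RNA of diploid budding yeast of the SK1 strain, a background that sporulates quickly and in synchrony, was measured on 24 spotted 2-colour arrays. The series holds 12 samples, taken at 0.0, 0.5, 1.0, 1.5, 2.0, 2.5, 3.5, 4.0, 4.5, 5.0, 5.5 and 6.0 h of sporulation. A 3.0 h sample was not analysed here. Per the labels, each sample pooled cells of 6 synchronized cultures grown side by side, and each was hybridised against RNA of time zero on 2 arrays with the dyes exchanged. The A array carried the later RNA in Cy5 and the B array carried it in Cy3.

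The deposited array files hold, per spot, an integrated intensity for each dye, a local background intensity and quality letters. Per the file headers, 2 scanned images were quantified per array; the software settings are not given in the sources used here. The deposited intensity values were taken as having the local background already subtracted, since negative values occur among them; the files do not state it. The dye of each channel was taken from the labels and the headers. The authors' series table holds 1 log2 ratio per gene and sample; how it was normalised is not given in the sources used here. Set against the arrays, 11 of its 12 columns followed the log2 ratio of the later time over time zero averaged over both arrays, with r from 0.878 to 0.964. The 0.5 h column did not, with r = 0.158. Column medians lay between -0.01 and 0.06. Scale and centring were read from the values alone.

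Each array has 13056 spots, of which 12614 carry genes, 250 are blank and 192 carry Arabidopsis controls. Control spots and spots marked U or Z were left out, as were spots with a value at or below 0 in either channel. Log2 ratios were corrected for intensity with loess (span 0.3, 4 iterations), B arrays were turned by sign, the 2 spots of a gene were averaged, and the A and B arrays of a time were averaged to 1 value, since they are technical repeats of the same RNA. Of 6293 array genes, 6283 had a value at every time and were tested. Symbols came from the R64 gene table by locus tag for 5716 identifiers and by an older name for 57, while 520 kept the identifier of the array. No coordinates are given, because the array files name no genome build.

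The tests, the windows, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The arrays led to 2 departures from that plan. Background correction with normexp and an offset of 50 had been planned as the standard treatment unless the values were already background-corrected; since they were taken as such, it became an alternative. Marked spots were to be left out, but the letters are not explained in the files and the letter S sat on the brightest spots, so spots marked S were kept as saturated ones would be. That decision followed a first run without them, which had called 120 genes between the late and middle windows where the reported treatment calls 228. Both alternatives call fewer genes there, and their counts are given with the dependence on processing.

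With R 4.3.3, limma 3.58.1 and jsonlite 2.0.0, a linear model with 4 window means was fitted to all 12 samples, with empirical Bayes moderation and Benjamini-Hochberg adjustment at 5%. The early window held 4 samples (0.5 to 2.0 h), the middle window 4 (2.5 to 4.5 h), the late window 3 (5.0 to 6.0 h), and zero was the 0.0 h sample alone, assumed to vary like the others. A second limma model used a natural spline of time with 3 degrees of freedom. Each time is 1 pooled sample, so p-values measure the spread between successive times of a window, which includes real change within it. The number of arrays limits the precision.

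A total of 22 gene lists were tested over the 4 contrasts with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The lists cover meiotic recombination, premeiotic replication, cohesion, middle sporulation genes, spore wall genes, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, the tricarboxylic acid cycle, acetate use, the respiratory chain, glycolysis, nitrogen catabolite repression, autophagy, amino acid biosynthesis, stress response, peroxisomes, histones, the proteasome, regulators of meiosis, and markers of vegetative and of haploid cells. Named genes were the 8 largest called rises and the 8 largest called falls per contrast for which both dye orientations gave the direction. Up to 4 members of each list with the smallest adjusted p were added. Every regulator was to be named where regulators are spoken of, which is done for late against middle only.

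A gene counted as above background in a channel when its mean exceeded the 95th percentile of the blank spots. The share of genes above background ran from 23.9% to 89.2% in the sample channel and from 17.6% to 84.5% in the time-zero channel. Where a gene was not above background on any array of a window, only a lower bound of its fold is given where it was called, from single-channel values after loess and Aquantile normalisation between arrays. Duplicate spots within an array correlated with a median r of 0.875.

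The code was tested on simulated data over 6283 genes with 100 genes changed by a log2 value of 2 and 100 by 4. It recovered 72% and 98% between the late and middle windows, 85% and 99% between the middle and early windows, 40% and 89% for early against zero, 42% and 88% for late against zero, and 44% and 83% over time. The simulated noise was normal and independent between genes and times, with no background floor and no separate A and B arrays. These shares therefore test the code and do not show which changes the real arrays could have missed. Alternatives covered background, normalisation, dim genes, dye orientation, window limits, thresholds, array weights, spline terms, the authors' table and each time left out in turn. All array headers share 1 processing date, so no batch could be tested. Figures were drawn with matplotlib 3.10.9.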

Results

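The arrays followed RNA levels through the first 6.0 h of sporulation, the programme in which starved diploid yeast goes through meiosis and packs the products into spores. All values are log2 ratios of a time over time zero, and changes between windows are differences of window means with the standard error (SE) of the limma fit. The A and B arrays of a time correlated across genes with a median r of 0.270, from -0.02 at 6.0 h to 0.577 at 1.5 h. Genes are not independent replicates. Arrays of the same dye orientation never correlated below -0.22.

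**Figure D1:**
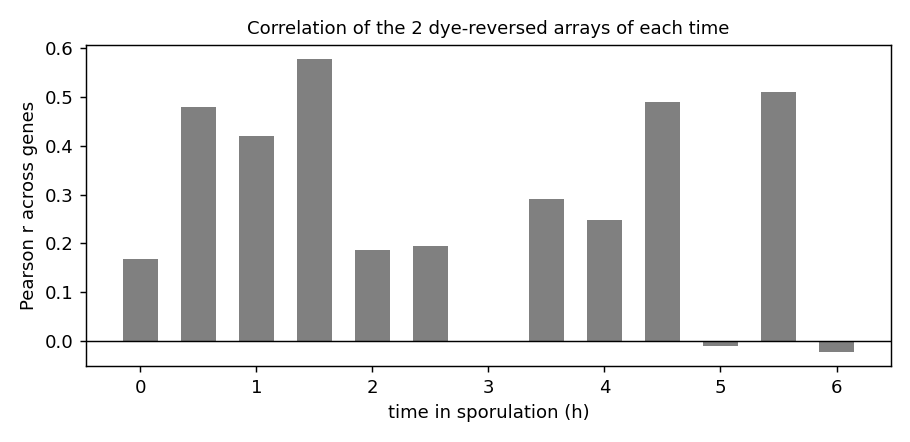
Pearson correlation across genes (y axis) between the A and B arrays of each time (x axis, hours); each bar is 1 time, measured on 2 arrays. The bars at 5.0 h (-0.01) and 6.0 h (-0.02) lie at 0, and the highest is at 1.5 h (0.577).

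The first comparison asked which genes differed in the first hours from time zero. Among genes for ribosome assembly, NOP58 and NOP56, core proteins of the box C/D particles that methylate ribosomal RNA, were at -2.34 ± 0.60 and -2.68 ± 0.70 (SE, n = 4 against 1), and CBF5, the pseudouridine synthase of the box H/ACA particles, at -2.99 ± 0.89. The heat-shock chaperone gene SSA4 was at -3.46 ± 0.64, with the cell wall gene SPI1 at -2.57 ± 0.72 and the small heat-shock protein gene HSP42 at -1.78 ± 0.58. In amino acid synthesis, HIS3 of the histidine pathway was at 2.95 ± 0.80 and LYS1 of the lysine pathway at 2.17 ± 0.56, whereas LYS2 was at -1.44 ± 0.44. Early arrays on which the later RNA was above background numbered 1 of 8 for NOP56, 2 for NOP58 and LYS2 and 4 for CBF5. None of these genes passed the test alone: limma called 0 of 6283 genes, with 369 at an unadjusted p under 0.05.

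By camera at the preset correlation, 7 of 22 lists shifted. Ribosome biogenesis fell (median -0.60, adjusted p = 2.47e-08, and adjusted p = 0.361 with an estimated correlation), with 0 of 53 members passing over all genes and 3 falling when adjusted over the list alone. Glycolysis fell (median -1.04), with HXK1 at -1.99 ± 0.65 and GPM1, phosphoglycerate mutase, at -1.37 ± 0.62; all 17 members lay below 0, and its adjusted p = 0.647 with an estimated correlation. The stress list fell by a median of 0.59 with 1 member falling when adjusted over the list alone, and the cytosolic ribosomal proteins fell by 0.25 with 0; their adjusted p = 0.642 and adjusted p = 0.890 with an estimated correlation. Amino acid biosynthesis rose (median 0.82, with 46 of 49 members above 0), as did histones (1.17) and premeiotic replication (0.25), each with 0 members passing, also when adjusted over the list alone, and each with adjusted p = 0.642 with an estimated correlation. The histone median peaked at 2.56 at 1.5 h; the linker histone gene HHO1 was at 2.21 ± 1.09 and the clamp loader gene RFC4 at 1.64 ± 0.62. On the 0.0 h A array, which set time-zero RNA against itself, the recombination list had a median of 0.83, against 0.02 on the B array. With the window set against a ratio of 0 in place of the 0.0 h sample, limma called 704 genes, 306 up and 398 down.

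The second comparison set the middle window against the early one. NOP58 was higher by 1.69 ± 0.38 (n = 4 against 4), and MPP10 and BRX1, which act in small and large subunit assembly, by 1.55 ± 0.37 and 1.19 ± 0.29; on the early arrays these were above background on 2 of 8, 1 of 8 and 1 of 8. The ribosomal protein genes RPL16B and RPS4A were higher by 1.36 ± 0.39 and 1.51 ± 0.45, and the glycolytic genes PGK1 and HXK1 by 1.28 ± 0.53 and 1.04 ± 0.41. The cytochrome genes CYC1 and CYT1 were at -1.63 ± 0.48 and -1.59 ± 0.57, SFC1, the mitochondrial succinate-fumarate carrier, at -2.08 ± 0.71, and the proteasome gene PRE6 at -1.54 ± 0.44. No gene passed: limma called 0, with 459 at an unadjusted p under 0.05, and 1 without the 4.0 h sample.

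At the preset correlation 12 lists shifted. Ribosome biogenesis rose (median 0.37; 9 of 53 members rose when adjusted over the list alone), with adjusted p = 0.361 with an estimated correlation. Cytosolic ribosomal proteins (0.36), glycolysis (1.01), amino acid biosynthesis (0.22), middle sporulation genes (0.34) and haploid mating genes (0.42) also rose, with 0 members passing when adjusted over each list alone. The 3.5 h sample stood apart, with a glycolysis median of -2.19 against 0.36 to 0.69 in the other middle samples. At that time the middle sporulation genes were high on the B array only. The respiratory chain (-0.56), acetate use (-0.54), premeiotic replication (-0.40), histones (-0.74), the proteasome (-0.26) and the regulators (-0.31) fell, again with 0 members passing when adjusted over each list alone. For these 11 lists the adjusted p lay between 0.361 and 0.863 with an estimated correlation. In 4 of them the median changed sign: the ribosomal proteins were at -0.14 from the B arrays alone and acetate use at 0.029 from the A arrays alone, while without the 2.5 and 4.5 h samples amino acid biosynthesis was at -0.16 and the proteasome at 0.027. In the middle sporulation list MPC54, a spore membrane gene, was at -1.82 ± 0.51, opposite to its list. In the regulator list 0 of 20 members passed and values ran from -1.59 to 0.97. The cyclin-dependent kinase inhibitor gene SIC1 was at -1.20 ± 0.45.

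The third comparison, late against middle, showed the largest count of changed genes. Genes that build the spore rose: CDA2 and CDA1, the chitin deacetylases that make the chitosan layer, by 4.65 ± 0.66 and 3.67 ± 0.61 (SE, n = 3 against 4), OSW1, needed for the outer spore wall, by 4.46 ± 0.49, GAS2, a glucan-remodelling enzyme, by 4.64 ± 0.67 and SMA1, of spore membrane assembly, by 4.57 ± 0.91. SPR3, a septin of the spore membrane, was not above background on any middle array and rose at least 5.84-fold. NDT80, the transcription factor that starts the middle genes, rose by 3.27 ± 0.49 and CDC20, an activator of the anaphase-promoting complex, by 2.62 ± 0.36. Middle arrays on which these genes were above background numbered 1 of 8 for CDA2, GAS2 and OSW1, 2 for CDC20, 3 for CDA1 and NDT80 and 4 for SMA1. Late arrays numbered 3 of 6 for CDA1, CDC20 and NDT80 and 4 of 6 for CDA2, GAS2, OSW1, SMA1 and SPR3. The SE was taken after the A and B arrays of a time were averaged. It does not measure their disagreement, which was large at 5.0 h (r = -0.01) and 6.0 h (r = -0.02). MEP2, an ammonium permease induced in nitrogen starvation, fell by 3.65 ± 0.75, the ribosomal protein genes RPL12B and RPS2 fell by 2.28 ± 0.58 and 2.01 ± 0.49, and NSR1, a nucleolar protein gene, fell by 2.06 ± 0.53.

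**Figure D2:**
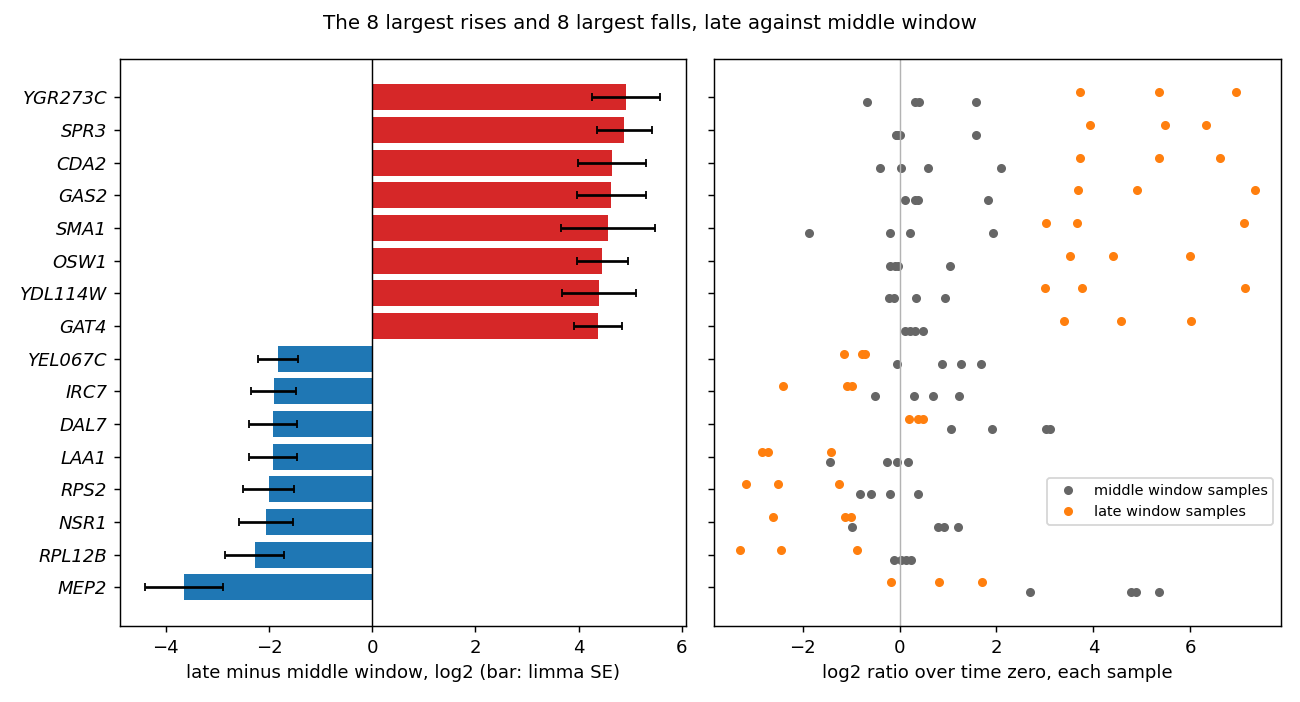
Left, the change from the middle to the late window on the log2 scale for the 8 largest rises and 8 largest falls, with bars for the limma SE; right, each sample's log2 ratio over time zero, 4 middle and 3 late samples per gene. The rise of YGR273C (4.92) is the largest drawn, though this gene was above background on only 1 of 8 middle arrays. The fall of MEP2 (-3.65) is the deepest. The bar of SPR3 is a fitted value, since it was not above background on any middle array.

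Limma called 228 genes, 208 up and 20 down, and for 212 of them (192 up, 20 down) the mean of the A arrays and the mean of the B arrays each gave the same direction. By the stricter count of every late array against the middle mean of its orientation, 46 of them (39 up, 7 down) did. Other large rises were YGR273C (4.92 ± 0.66), YDL114W (4.40 ± 0.72) and GAT4, a GATA-family zinc finger gene (4.37 ± 0.47). YGR273C was above background on 1 of 8 middle and 5 of 6 late arrays, and YDL114W and GAT4 on 2 and 4. The single-channel means of YGR273C were 15.37 in the middle and 17.89 in the late window, a smaller step than its ratio change. Other falls were LAA1 (-1.92 ± 0.47), DAL7, the malate synthase of allantoin use (-1.92 ± 0.46), IRC7 (-1.91 ± 0.44) and YEL067C (-1.82 ± 0.39). LAA1 was above background on 2 of 8 middle and 1 of 6 late arrays, YEL067C on 4 and 2, NSR1 on 6 and 2, RPS2 on 8 and 3, IRC7 on 7 and 4, and MEP2, RPL12B and DAL7 on at least 7 and 5. Of the 228 genes, 52 were above background on 1 middle array or none, YGR273C, CDA2, GAS2 and OSW1 included. For 37, among them SMA1, YDL114W, SPO11, ORC1 and LAA1, the single-channel means differed by under 0.5 of the ratio change. The sizes of both sets of changes are uncertain.

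Of the 45 middle sporulation genes, 26 rose, 0 fell and 19 did not pass; 34 rose when adjusted over the list alone. The list's median was 2.58 (adjusted p = 4.89e-29; adjusted p = 0.336 with an estimated correlation). SPO21 and SSP1, which act in the formation of the spore membrane, rose at least 2.61-fold and at least 2.22-fold. Both, and DIT2 below, were above background on 3 of 6 late arrays. Of 16 spore wall genes 6 rose and 10 did not pass (9 rose when adjusted over the list alone; median 1.55; adjusted p = 0.336 with an estimated correlation), with DTR1, a bisformyl dityrosine transporter, up by 3.17 ± 0.48 and DIT2, a dityrosine enzyme, up at least 1.83-fold. Of 31 recombination genes 7 rose and 24 did not pass (10 rose when adjusted over the list alone; median 1.21; adjusted p = 0.361 with an estimated correlation). Among them were MAM1, a monopolin subunit that joins sister kinetochores, at 3.01 ± 0.40, SPO11, the nuclease that starts recombination, at 2.16 ± 0.30, MEI4 at 1.86 ± 0.35 and MND1 at 1.68 ± 0.33, above background on 1, 4, 3 and 1 of 8 middle arrays and on 3, 4, 3 and 3 of 6 late arrays.

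Cytosolic ribosomal proteins fell, with a median of -1.13; 4 of 133 fell, including RPS14B (-1.51 ± 0.38) and RPS16B (-1.36 ± 0.34), and 59 fell when adjusted over the list alone (adjusted p = 4.71e-26; adjusted p = 0.368 with an estimated correlation). Ribosome biogenesis (median -0.51; 1 of 53 fell), glycolysis (-0.83; 1 of 17, HXK2 at -1.44 ± 0.31, above background on 2 of 8 middle and 3 of 6 late arrays), nitrogen catabolite repression targets (-0.79; 2 of 25, MEP2 and DAL7) and amino acid biosynthesis (-0.73; 0 of 49 fell, while SER33, of serine synthesis, rose by 2.13 ± 0.47) also fell. Adjusted over the list alone, 0, 1, 2 and 0 members fell, and the lists' adjusted p lay between 0.404 and 0.647 with an estimated correlation. Mitochondrial ribosomal proteins (0.36), the proteasome (0.55) and the regulators (0.35) rose, with adjusted p = 0.647, adjusted p = 0.745 and adjusted p = 0.361 with an estimated correlation. Of the mitochondrial ribosomal proteins 0 rose and MRPL6 fell by 1.31 ± 0.32, while 0 of 33 proteasome genes passed; adjusted over the list alone both gave 0. Of 20 regulators NDT80 and CDC20 rose, and 3 rose when adjusted over the list alone. The other 18 (IME1, IME2, IME4, SUM1, UME6, RIM4, RIM11, RIM15, RIM101, MCK1, SIN3, RPD3, SWE1, CDC28, CKS1, SIC1, CDC7 and DBF4) lay between -0.24 and 1.44 and did not pass.

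Lists without a shift held called members too. PDS1, the securin, and SGO1, the shugoshin that protects centromeric cohesion, rose by 3.17 ± 0.65 and 2.29 ± 0.33 among 11 cohesion genes, and the S-phase cyclin gene CLB6 and the origin gene ORC1 rose by 2.98 ± 0.32 and 1.99 ± 0.32 among 38 replication genes. PDS1 and SGO1 were above background on 2 and 4 of 8 middle arrays and on 4 of 6 late arrays, and CLB6 and ORC1 on 1 of 8 and 3 of 6. Adjusted over the list alone each list again had 2 rises. The count of 228 depended on single times: it was 140 without the 2.5 h sample, 143 without 4.5 h, 124 without 5.5 h and 466 without 6.0 h. It was 0 from the A arrays alone (810 at an unadjusted p under 0.05) and 0 from the B arrays alone (946), 0 with windows ending at 1.5 and 4.0 h (542), 36 with scaling between arrays, 120 with S-marked spots left out, and 89 with normexp.

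**Figure D3:**
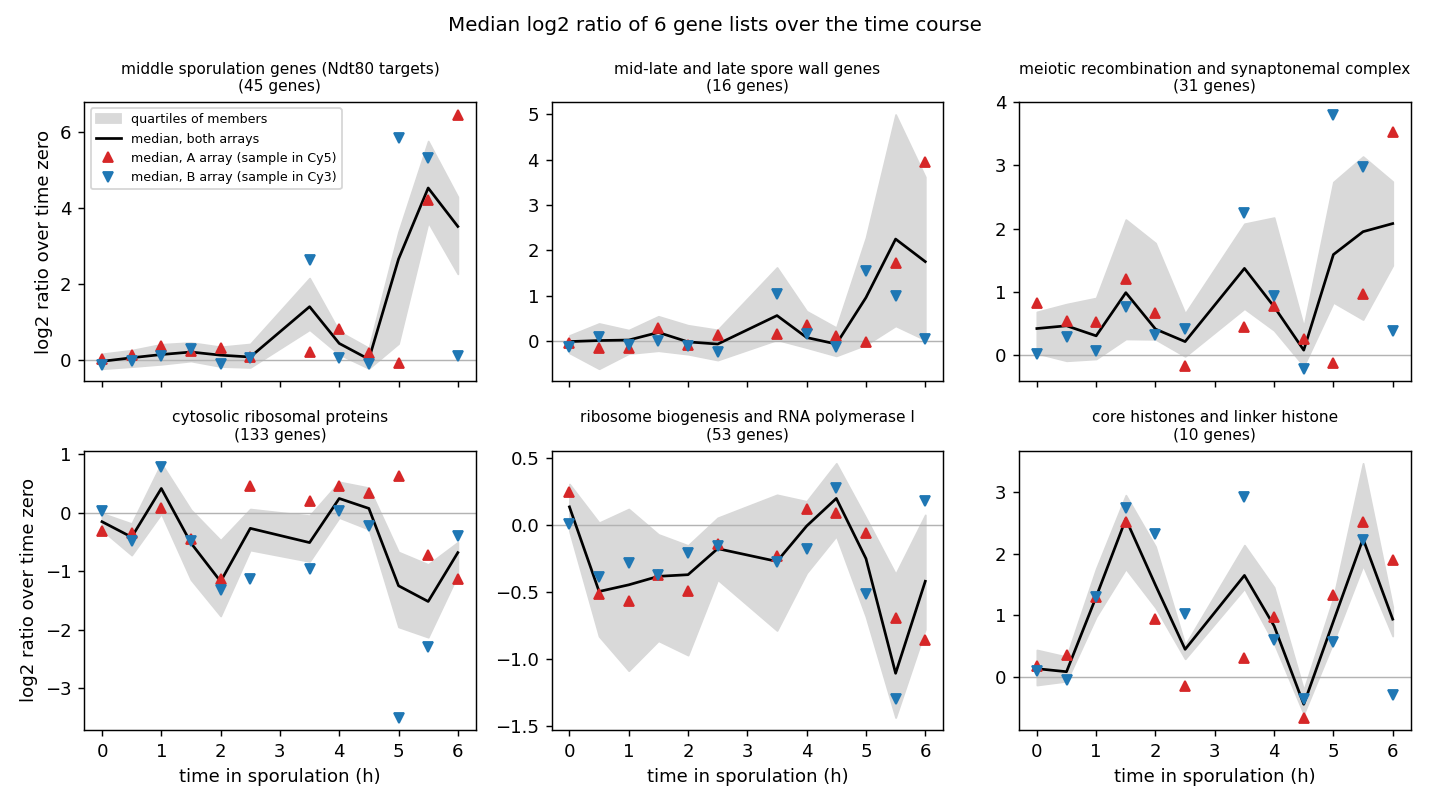
Median log2 ratio over time zero of 6 gene lists (y axis) against time in hours (x axis); the line is the median over both arrays, the band the quartiles of the members, and the triangles the median on each array. The middle sporulation median reached 4.52 at 5.5 h, while at 5.0 h the A array gave -0.09 and the B array 5.83, and at 6.0 h they gave 6.45 and 0.09.

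The fourth comparison gave the net change from time zero to the late window. SPR1, a spore-specific glucanase gene, rose by 5.80 ± 1.23 (n = 3 against 1), CNM67, a spindle pole body gene, by 3.56 ± 0.63 and YNL034W by 3.43 ± 0.57. Genes not above background in the time-zero channel of any late array have lower bounds: YGR273C rose at least 8.69-fold, CDA2 at least 8.31-fold, SMA2 at least 5.46-fold, YGL230C at least 5.18-fold, MEI4 at least 4.16-fold, NDT80 at least 3.96-fold, SPO21 at least 3.51-fold, MAM1 at least 3.17-fold, SSP1 at least 2.996-fold, DIT2 at least 2.25-fold and CLB6 at least 2.08-fold. SPR3 rose by 6.70 ± 0.81, CDA1 by 4.71 ± 0.92, PES4 by 3.77 ± 0.55, DTR1 by 3.75 ± 0.73 and CDC20 by 2.91 ± 0.54. In the time-zero channel SPR1, CNM67, SPR3 and PES4 were above background on 1 of the 6 late arrays, and YNL034W, CDA1, DTR1 and CDC20 on 2. The later RNA was above background on 3 of the 6 late arrays for MEI4, NDT80, SPO21, MAM1, SSP1, DIT2, CLB6, CNM67, CDA1 and CDC20. It was above background on 4 for SPR1, CDA2, SMA2, YGL230C, SPR3, PES4 and DTR1, and on 5 for YGR273C and YNL034W.

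Limma called 56 genes, all 56 up, with 734 at an unadjusted p under 0.05. All 56 were also among the 208 rises from the middle window. Both contrasts use the same late samples in 1 fit, so this overlap is no independent evidence. For 13 of the 56 both arrays gave a rise at every late time, and 27 were not above background in the time-zero channel of any late array. SPR3, CDA2, CDA1, SSP1, SPO21, PES4 and DTR1 were not among these 13, so the sizes of their rises are uncertain. Middle sporulation genes rose (median 3.36; 15 of 45 up, 30 not passing, 31 up when adjusted over the list alone), as did spore wall genes (1.74; 5 of 16, and 6 when adjusted over the list alone) and recombination genes (1.40; 2 of 31, and 5 when adjusted over the list alone). Their adjusted p lay between 0.336 and 0.361 with an estimated correlation. Histones rose (1.23, 0 of 10 passing, also when adjusted over the list alone; adjusted p = 0.739 with an estimated correlation). Cytosolic ribosomal proteins (-0.996), ribosome biogenesis (-0.72), acetate use (-0.77), the respiratory chain (-0.68), glycolysis (-1.12) and the stress list (-0.63) fell with 0 members passing, and adjusted p between 0.361 and 0.739 with an estimated correlation. Adjusted over the list alone, 1 glycolysis gene fell and 0 in the others. RPL10 was at -2.09 ± 0.60, FBP1, of gluconeogenesis, at -2.95 ± 0.85, HXK2 at -2.04 ± 0.47 and SPI1 at -2.70 ± 0.75, none passing. The count was 28 without the 1.0 h sample, 31 without 1.5 h, 85 without 5.0 h and 114 without 6.0 h, and 0 from either dye orientation alone (561 and 281 at an unadjusted p under 0.05), 0 without the dimmest genes (501) and 0 without genes rarely above the blanks (566). With scaling between arrays it was 33, 26 up and 7 down, with normexp 9, and with the ratio set against 0, which leaves out the spread of the control, 1422, 882 up and 540 down.

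Of the 88 pairs of list and contrast, 40 shifted at the preset correlation, 19 up and 21 down, and 0 with an estimated correlation, where 10 had an unadjusted p under 0.05. The lists for the tricarboxylic acid cycle (medians from -0.62 to 0.48), cohesion (-0.20 to 0.10), autophagy (-0.05 to 0.26), peroxisomes (-0.18 to 0.04) and vegetative growth (-0.06 to 0.17) shifted in no contrast. In 8 pairs the median, the mean and the test differed in sign, and none of these pairs passed.

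The spline over time called 40 genes, 37 up and 3 down, with 820 at an unadjusted p under 0.05. The 3 falls, picked out after their values were seen, were URA1, of pyrimidine synthesis, at -3.76, NCE103, carbonic anhydrase, at -1.81, and NSA2, of large ribosomal subunit assembly, at -1.42, each as the fitted last value minus the first. Of the 40 genes, 33 were also called between the late and middle windows and 24 between the late window and zero. The count was 3 without the 0.0 h sample, 0 without 0.5 h, 0 without 1.0 h, 1 without 1.5 h, 1 without 2.0 h, 21 without 2.5 h, 13 without 4.0 h, 87 without 4.5 h, 4 without 5.0 h, 0 without 5.5 h and 146 without 6.0 h. It was 0 with normexp (637 at an unadjusted p under 0.05), 0 with scaling between arrays (802) and 0 from the B arrays alone (412), but 262 (214 up, 48 down) from the A arrays alone and 446 without the 6.0 h B array.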

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

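The search for samples far from the others of their window was planned; of the tests below, those of dim signal at 3.5 h, of another time's RNA, of poor hybridisation, of the 4.5 h sample and of the 0.5 h column were chosen after the result was seen, as was the choice of patterns.

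Among 132 windows of 4 samples, 9 held a value far from the other 3; chance alone gives about 1 in 20. Of these, 5 lay at 3.5 h. There the glycolysis median was -2.19 and PGK1, phosphoglycerate kinase, was at -2.01, against 0.36 to 0.69 for the glycolysis median in the other middle samples. The later RNA of PGK1 was above background on the 3.5 h B array but not on the A array, where 25.2% of genes were. The size of its fall is therefore uncertain. The spore genes SPR3 (1.57), GAS2 (1.83) and OSW1 (1.04) made up the other 3 at 3.5 h, where GAS2 and OSW1 were above background on the B array and on no other middle array, with the time-zero channel above it on 0 arrays, so the size of their ratios is uncertain. SPR3 was above background on 0 of the 8 middle arrays, so its ratio does not show that it was high. LYS1 was low at 1.5 h (0.82), MPC54 high at 1.5 h (2.93), MPP10 high at 4.0 h (0.51) and SGO1 low at 4.5 h (-0.21).

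The middle sporulation genes were high on 1 of the 2 arrays at 3.5 h (medians 0.21 on A and 2.62 on B), at 5.0 h (-0.09 and 5.83) and at 6.0 h (6.45 and 0.09); per the labels both arrays of a time carry the same RNA, so no biological explanation was tested. The genes brightest over all arrays gave r = 0.00134 between A and B at 5.0 h and r = -0.110 at 6.0 h. At 3.5 h they gave r = 0.338 (0.291 over all genes), so dim signal is not argued against there. An array dim as a whole would also give a low r. At 5.0 h 62.9% (A) and 80.1% (B) of genes were above background in the sample channel, so dim signal is argued against. At 6.0 h these shares were 87.3% and 28.8%, so the test cannot decide. The 5.0 h A array may hold RNA of another time, as it correlated with the 4.0 h A array at r = 0.637 and with its own B array at -0.01. That test does not single it out: 7 of the 24 arrays were closer to another time than to their own by 0.3 or more, among them the 5.0 h B array (0.718 with 5.5 h B) and the 3.5 h B array (0.653 with 6.0 h A). For 6.0 h, poor hybridisation of the B array stays a candidate: its duplicate spots correlated with r = 0.670, against 0.758 for the next lowest array after 0.0 h. That r cannot decide it, since such an r also falls where log ratios are small. Their standard deviation was 0.726 on this array and 1.63 on the 6.0 h A array. The 4.5 h B array, at 0.786, still gave a duplicate r of 0.937.

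At 4.5 h the medians of the middle sporulation (0.008), recombination (0.082) and histone (-0.44) lists lay below those at 4.0 h (0.43, 0.77 and 0.83) and 5.0 h (2.65, 1.59 and 0.90), whereas amino acid biosynthesis (1.05) was close to 4.0 h (0.90). The A and B arrays at 5.0 h disagreed on the middle sporulation list, as given above. Its A median there lay below the 4.5 h median, so its drop against 5.0 h rests on the B array. Over all genes, noise is argued against, since the 4.5 h A and B arrays correlated with r = 0.490, above the median of 0.270 over all times. That r cannot decide for dim members of these lists. On the 4.5 h A array only 23.9% of genes were above background in the sample channel. A mislabelled sample may be a candidate explanation, as it correlated with 2.5 h at r = 0.535 and with its closer neighbour at 0.347. That test does not single it out: the 3.5 h sample correlated with 1.5 h at r = 0.590 and with its closer neighbour at 0.351. The likeness of 4.5 h to 2.5 h was also uneven, with r = 0.713 between the A arrays and r = 0.206 between the B arrays. A real passing change was not tested and stays open.

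The authors' 0.5 h column followed the difference of the B and A arrays at r = 0.714 and their mean at 0.158, which may mean that the sign of 1 array was not turned. That column enters only the alternative that uses the authors' table.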

How the results depend on the processing

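Most alternatives were planned; those with normexp, S-marked or X- and Y-marked spots, single arrays left out, pairs of times left out, the 0.0 h B array or genes rarely above the blanks were chosen after seeing the data, as was the test of splits for the middle against the early window. The cause of each change was not tested unless named.

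The late against middle count of 228 became 89 with normexp, 94 with median centring, 36 with scaling between arrays, 117 without the dimmest genes, 0 with A arrays, 0 with B arrays, 96 at 1%, 0 with windows ending at 1.5 and 4.0 h, 62 with windows ending at 2.5 and 5.0 h, 120 without S-marked spots, 100 without X- and Y-marked spots and 129 without genes rarely above the blanks. It was 21 without the 2.5 and 4.5 h samples and 702 without the 5.0 and 6.0 h samples. It was 495 without the 6.0 h B array and 984 (661 up, 323 down) without the 5.0 h A and 6.0 h B arrays. These last arrays were picked for what they measured, so the higher counts are no independent evidence. Leaving out single times gave 124 to 466.

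The late against zero count of 56 became 9 with normexp, 29 with median centring, 33 (26 up, 7 down) with scaling, 0 without the dimmest genes, 0 with A arrays, 0 with B arrays, 8 at 1%, 1422 against a ratio of 0, 26 without S-marked spots, 12 without X- and Y-marked spots, 90 without the 6.0 h B array, 322 without the 5.0 h A and 6.0 h B arrays, 334 without the 5.0 and 6.0 h samples and 0 without genes rarely above the blanks. Single times left out gave 28 to 114. Without the 0.0 h sample neither contrast with zero has a value.

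The early against zero count of 0 became 1 with normexp, 12 with scaling, 1 with A arrays, 704 against a ratio of 0, 1 with windows ending at 1.5 and 4.0 h and 1 without X- and Y-marked spots, and 0 to 0 without single times. The middle against early count of 0 became 1 without the 2.5 and 4.5 h samples, and 0 to 1 without single times.

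The spline count of 40 became 1 without background correction, 0 with normexp, 25 with median centring, 0 with scaling, 9 with the authors' table, 9 without the dimmest genes, 262 with A arrays, 0 with B arrays, 0 at 1%, 65 with 2 and 3 with 4 degrees of freedom, 6 with a straight line, 3 without the 0.0 h sample, 11 without S-marked spots, 446 without the 6.0 h B array, 212 without the 5.0 h A and 6.0 h B arrays, 66 without the 2.5 and 4.5 h samples, 0 without the 5.0 and 6.0 h samples and 11 without genes rarely above the blanks. Single times left out gave 0 to 146. The 40 list shifts became 0 with an estimated correlation and 23 to 42 without single times; without the 0.0 h sample only the contrasts between windows could be tested.

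All 6 changes of sign were in the middle against early comparison; that of NOP2 (-0.044 with B arrays), not above background on any early array, carries no information. With A arrays the acetate list was at 0.029; with B arrays the cytosolic ribosomal proteins were at -0.14; with windows ending at 1.5 and 4.0 h HHO1 was at 0.61; without the 2.5 and 4.5 h samples amino acid biosynthesis was at -0.16 and the proteasome at 0.027. Over all alternatives, the called genes that the text names kept direction and call in 1123 of their values and lost the call in 500. Most were named for large changes or small adjusted p, so this does not describe the other called genes. Called lists kept both in 1028 and lost the call in 151.

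Other splits of the same samples bear on chance. For late against middle, 1 of 35 splits, the real one, called as many genes (228, highest other 94). The next split grouped 2.5, 4.0 and 4.5 h. Neighbouring times resemble each other (r = 0.703 between 5.0 and 5.5 h), and the real split groups neighbours. The splits are therefore not equivalent, and this test cannot exclude chance. For the spline, 3 of 100 orders, the real one included, called as many (40, highest other 65), a share under the limit of 0.05 used here. The real count lies within the range of the other orders. Shuffled orders also break the likeness of neighbouring times, so chance is not excluded. For middle against early the real count was 0 (highest other 22), so 35 of 35 splits reach it by construction and the test says nothing about chance. Chance is not excluded for the lists, where 11 of 35 splits gave as many between late and middle (11, highest other 14) and 6 of 35 between middle and early (12, highest other 15). Signal over background limits the low end, as 19 of the 228 genes were not above the blanks on any middle array.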

Other observations

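The lists of the next paragraph were chosen after the called genes were seen, so their counts describe these genes and test nothing.

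Between the middle and late windows, 5 of 13 subunits of the anaphase-promoting complex, the ubiquitin ligase that drives chromosome separation, rose: APC1 by 2.07 ± 0.32, APC4 by 1.93 ± 0.38, APC11 by 2.31 ± 0.44, CDC16 by 2.24 ± 0.38 and CDC27 by 2.08 ± 0.36 (SE, n = 3 against 4; limma). All 13 lay above 0, with a median of 1.46. Against zero limma called 0 of the 13, with 6 at an unadjusted p under 0.05. Of 16 genes of the spindle pole body, the yeast microtubule-organising centre, 5 rose and 0 fell. These were CNM67 (3.65 ± 0.42), SPC29 (3.26 ± 0.76), BBP1 (2.30 ± 0.44), MPS1 (2.29 ± 0.33) and SPC42, which was not above background on any middle array. Against zero 1 of the 16 was called. The median between the middle and late windows was 0.69, and TUB4, the gamma-tubulin gene, was at -0.33 ± 0.35.

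ATG3 and ATG4, which act in the lipid conjugation of Atg8 in autophagy, rose by 1.92 ± 0.42 and 1.74 ± 0.34 between the middle and late windows, the 2 called members of 25 in a list fixed beforehand that did not shift as a group.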
